A study of Mus musculus with 32 samples.

How the data were processed

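Total RNA from dissected tumor and from the stroma around it was labelled with Cy3 and hybridised to one-colour Agilent mouse arrays of 62976 spots, 59305 of them not controls. Per the labels' protocols the RNA was prepared with a fibrous tissue kit, had an integrity number above 7, and 200 ng entered the labelling. Signals were extracted with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited files hold the processed signal as an intensity on a linear scale, per the file headers, and log2 values were taken from it here. The deposited series matrix holds log2 values that the authors scaled to the 75th percentile and centred, for each probe, on its median within a tissue. That scale was checked on 56745 probes. Over all probes and arrays 99.8% of values in stroma and 99.7% in tumor lay within 0.01 of the value computed here. The column medians of the series matrix ran from -0.315 to 0.563. Because of this centring the series matrix was not used to compare the tissues.

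Outlier spots (58 to 483 per array, most on wild-type tumor 5) were left out and replicate spots of a probe averaged, which left 1275 missing values. The 75th percentile of the processed signal ran from 584 to 1727. Each value was the log2 intensity minus that of the array's 75th percentile. Of 56605 non-control probes 32994 matched a RefSeq name (GRCm38.p6, used for names and neighbours only), giving 22911 symbols, and 23611 were kept under the file's name. For each of 45616 names the probe with the highest mean over the 32 arrays was kept, since 7899 symbols had more than 1 probe. A gene was tested where it was well above background on at least 8 arrays of the fit and lacked at most 2 values.

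Tests used limma 3.58.1 (lmFit and eBayes) with statmod 1.5.0 and the data.table package (version 1.17.8) in R 4.3.3, and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Within each tissue 16 arrays were fitted with 1 mean per genotype and sex, and all 32 arrays were fitted for stroma against tumor and for genotype by tissue. Differences are knockout minus wild type, stroma minus tumor and male minus female, and interactions are stroma minus tumor or male minus female. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The 33 gene lists were tested with camera at a preset correlation of 0.01 where at least 5 genes were measured, and also with an estimated correlation and with fry. The fry test asks whether the genes of a set move on balance one way and does not compare them with other genes. Lists were adjusted within 1 comparison. These tests, the lists and the alternatives were chosen before the data were examined. Chosen after seeing the data were the fits without arrays against their sex label, without wild-type stroma 65 and 82 and without wild-type tumor 5, the brighter Xist probe, which matched no RefSeq name, the use of the median spot signal in place of the mean in the normexp correction, and the exact permutation of list means over 12870 splits of 8 against 8 arrays.

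Genes are named by rule: (a) Ptger2, its related receptors, the cyclooxygenases, Ptges, Hpgd and the sex-linked genes; (b) the 10 largest rises and falls among genes that passed, or the 5 smallest p in each direction where none did, well above background on all arrays of the brighter group and with a gene symbol; (c) up to 4 members of a list, or 2 where none passed. Some results that these rules select are not reported here. For interactions the brighter group was the brightest of the 4 groups for genotype by tissue and the brighter genotype for genotype by sex. Members under (c) were computed for the genotype comparisons, stroma against tumor, sex in tumor and genotype by tissue. Where the dimmer group was well above background on 0 arrays, an at-least fold is given. It is the mean of the brighter group minus the mean of the dimmer group, with each dim value raised to the lowest signal well above background on its array. The number of arrays beside a value counts those of the first group beyond the median of the other.

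Alternatives were normexp correction (offset 50) with quantile scaling, quantile scaling, the 75th percentile of probes bright on all arrays, the series matrix, no filter, a filter on all arrays, the mean of all probes, a trended robust variance, array weights, slide as a fixed or random block, all arrays in 1 fit, sex left out, 3 list means as covariates, replicate number as a block, each sex alone, 1.5-fold and 2-fold limits, an adjusted p under 0.1 and leaving out each array. Arrays lay on 6 slides scanned on 2 days. Slide 1 held no wild-type tumor and no knockout stroma, slide 5 no knockout tumor and slide 6 no wild-type tumor, so both genotypes shared 5 slides in stroma and 3 in tumor. Differences within slides are of plain array means, and on some slides genotype and sex label differed together. Slide 2 set wild-type stroma 65 (male) against knockout stroma 51 (female), and slide 4 wild-type stroma 9 (male) against knockout stroma 12 (female). Such a pair enters both the genotype and the sex counts.

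The tests were run on simulated data with 200 changed genes per comparison. With independent noise 21% of 2-fold and 78% of 4-fold changes were recovered for genotype in stroma (24673 genes), 50.0% and 91% for genotype in tumor (23550), 9% and 58% for genotype by tissue (26717) and 63% and 95% for stroma against tumor (26717). They were 23% and 71% for sex in stroma (24673), 48% and 82% for sex in tumor (23550), 0% and 10% for genotype by sex in stroma (24673) and 3% and 53% for genotype by sex in tumor (23550). False calls were 1.98% to 11.1%. With the arrays' own deviations as noise 44 of 172 calls were false for genotype in tumor (25.6%) and at most 2.35% in the other comparisons. Among genes with independent noise, a list raised by design was called by camera in stroma (adjusted p = 2.86e-14) and tumor (1.18e-21), with 0 other lists called. Genes of a list did not move together in that simulation. It therefore cannot show how often camera calls a list wrongly where they do.

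The labels give replicate numbers and do not say that these are separate animals, so p-values measure the spread between these samples. Arrays of 1 group were not duplicates: correlations ran from 0.789 to 0.976 in wild-type stroma, 0.928 to 0.986 in knockout stroma, 0.891 to 0.989 in wild-type tumor and 0.924 to 0.982 in knockout tumor.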

Results

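Gene expression was measured on 32 one-colour arrays from mice carrying MCG 101, a transplantable sarcoma first induced with methylcholanthrene. The hosts were wild type or lacked EP2, the prostaglandin E2 receptor encoded by Ptger2, which couples to Gs and raises cAMP. Each of the 4 groups, wild-type stroma, knockout stroma, wild-type tumor and knockout tumor, held 8 arrays, 4 labelled from female and 4 from male hosts. Between 49.99% of probes (the array labelled wild-type stroma 82) and 76.3% (wild-type tumor 5) were well above background, and no spot was saturated. The number of arrays limits the precision. In a principal component analysis the first component held 58.8% of the variance. On it the arrays labelled wild-type stroma 65 (-68.5) and 82 (-113) lay within the range of the tumor arrays (-161 to -30.8), while the other 14 stroma arrays ran from 21.9 to 228.

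The genotype labels were compared first with the signal of Ptger2 itself. Its log2 level, relative to the 75th percentile of each array, was -4.42, -3.62, -4.27, -2.58, -2.98, -4.40, -4.26 and -5.65 in wild-type stroma 1, 5, 45, 68, 4, 9, 65 and 82. In knockout stroma 12, 49, 51, 59B, 15, 81, 95 and 99 it was -2.82, -3.25, -2.80, -3.71, -2.38, -3.41, -3.84 and -3.15. In wild-type tumor 1, 5, 45, 68, 4, 9, 65 and 82 it was -4.46, -5.02, -6.18, -4.43, -5.51, -4.59, -6.14 and -3.46. In knockout tumor 12, an array whose number does not occur in stroma, 51, 59B, 15, 81, 95 and 99 it was -3.09, -4.81, -3.67, -5.27, -3.65, -3.08, -3.95 and -3.78. The single Ptger2 probe was therefore no lower in the knockout: its mean was -3.17 ± 0.49 (SD, n = 8) in knockout against -4.02 ± 0.96 (n = 8) in wild-type stroma, a log2 difference of 0.85 ± 0.37 (SE, adjusted p = 0.158). In tumor it was -3.91 ± 0.77 against -4.97 ± 0.93 (SD, n = 8 each), a difference of 1.06 ± 0.41 (SE, adjusted p = 0.976). All 8 knockout stroma arrays and 6 of 8 knockout tumor arrays lay above the wild-type median. Within slides the knockout was higher on 5 of 5 slides in stroma (0.42 to 1.58) and on 3 of 3 in tumor (1.02 to 3.1), and with slide as a fixed block the differences were 1.20 and 1.96. The within-slide counts do not separate genotype from sex. With array weights the stroma difference passed the test (0.87, adjusted p = 0.0128), but so did 16148 of 24781 genes under that setting. The levels were near background, with 6 of 8 wild-type stroma arrays and 3 of 8 wild-type tumor arrays well above it. The position of the probe relative to the deleted part of the gene is not known, so its signal checks no genotype label.

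**Figure D1:**
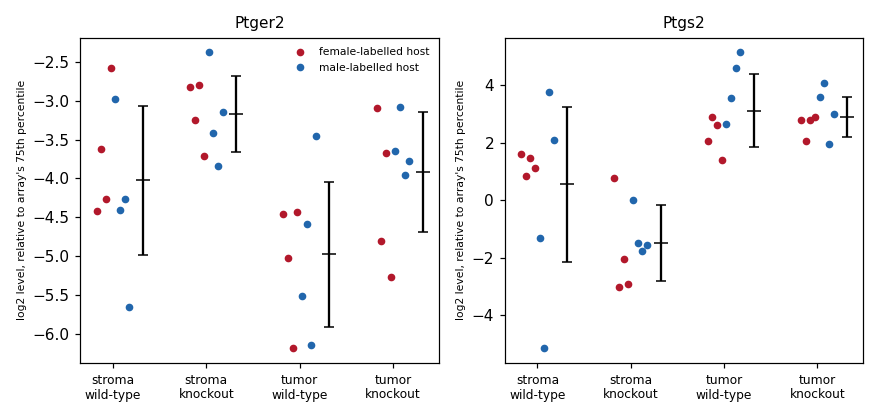
Log2 signal of Ptger2 and of Ptgs2 relative to each array's 75th percentile, by group; points are arrays, bars are the mean ± SD of 8 arrays. Ptger2 averaged -3.17 in knockout and -4.02 in wild-type stroma, and Ptgs2 averaged 3.12 in wild-type tumor and 0.56 in wild-type stroma.

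The next question was whether other genes of prostaglandin signalling differed with the host genotype, and none passed the test in either tissue. Ptgs2, the inducible cyclooxygenase, was at -1.50 ± 1.32 in knockout and 0.56 ± 2.70 in wild-type stroma (SD, n = 8 each), a difference of -2.06 ± 1.0 (SE, adjusted p = 0.188) with all 8 knockout arrays below the wild-type median. Within slides Ptgs2 was lower on 4 of 5 slides, with differences from -5.81 to 5.93. Ptgs1, the constitutive cyclooxygenase, differed by 0.89 ± 0.43 in stroma (adjusted p = 0.183, 8 of 8 arrays). Hpgd, which degrades prostaglandin E2, differed by 1.57 ± 0.64 (adjusted p = 0.143, 8 of 8 arrays), and Ptgir, the prostacyclin receptor, by 0.81 ± 0.29 (adjusted p = 0.122, 8 of 8 arrays). Ptger4, which encodes the other Gs-coupled prostaglandin E2 receptor, differed by 0.41 ± 0.34 (adjusted p = 0.405), and Ptger3 by 0.22 ± 0.77 (adjusted p = 0.855), turning to -0.02 after normexp correction and quantile scaling and to -0.73 without wild-type stroma 65 and 82. Ptges, the inducible prostaglandin E synthase, stood at 4.65 ± 0.35 and 4.66 ± 0.28 (difference -0.01 ± 0.18, adjusted p = 0.963), and its sign turned with quantile scaling (0.01) and with the 75th percentile of bright probes (0.07). In tumor, Ptgs2 differed by -0.22 ± 0.38, Ptger4 by 0.31 ± 0.24 and Ptgir by -0.81 ± 0.26 (adjusted p = 0.976 for each, 3, 7 and 8 of 8 arrays). Tumor Ptges differed by -0.07 ± 0.14 (adjusted p = 0.978, 0.06 with slide as a block) and Ptgs1 by -0.12 ± 0.48 (adjusted p = 0.985), the latter turning to 0.02 with quantile scaling. Without the arrays against their sex label the tumor difference was 0.12 for Ptgs2 and 0.04 for Ptgs1. Ptger1 was well above background on too few arrays to be tested in both tissues, as were Ptger3 and Hpgd in tumor. Of the 22 listed prostaglandin pathway genes 18 were tested in stroma, of which 10 were higher and 8 lower (median 0.32, camera adjusted p = 0.430), and 17 in tumor (median -0.08, adjusted p = 0.770).

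The comparison of knockout with wild-type stroma asked what the loss of EP2 in the host changed in the tissue around the tumor. No single gene passed the test, but groups of immune genes, muscle genes and fat genes were higher and cell cycle and ribosomal protein genes were lower in knockout stroma. With an estimated correlation no list was called (adjusted p = 0.693 for each of them). The single genes with the smallest p were Fbxl22, an F-box protein of striated muscle, at 3.49 ± 0.59 (SE, adjusted p = 0.113, 8 of 8 arrays), and Tnfaip2, a gene induced by tumor necrosis factor, at 1.57 ± 0.27 (adjusted p = 0.113, 8 of 8 arrays). Card14 (3.27 ± 0.58), Scn3b (2.96 ± 0.54) and Clu, the chaperone clusterin (1.87 ± 0.36), had an adjusted p of 0.120 and were higher on 8 of 8 arrays. On the lower side stood the homeobox gene Hoxa11 (-3.05 ± 0.57, adjusted p = 0.120), its antisense transcript Hoxa11os (-2.51 ± 0.40, adjusted p = 0.113) and Tenm3, a teneurin of neuronal wiring (-1.62 ± 0.27, adjusted p = 0.113). Snhg12 (-1.05 ± 0.19) and Ppp1r13l, an inhibitor of p53 (-0.88 ± 0.16), had an adjusted p of 0.120, and all 5 genes were lower on 8 of 8 arrays. Fbxl22 was at 3.84 and Tnfaip2 at 1.72 with slide as a fixed block (adjusted p = 0.237 for both).

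Among the immune lists, 9 of 9 measured B cell and plasma cell markers were higher in knockout stroma (median 1.32, camera adjusted p = 0.00179), none passing over all genes and 5 rising adjusted over the list alone. Cd22, an inhibitory receptor of B cells, differed by 0.79 ± 0.27 (SE, adjusted p = 0.122, 8 of 8 arrays), and the list was higher on 5 of 5 slides (1.31 to 2.12). Macrophage markers (16 of 18 higher, median 0.83, adjusted p = 0.00638) included the scavenger receptors Mrc1 (1.51 ± 0.49, adjusted p = 0.120) and Cd163 (1.98 ± 0.71, adjusted p = 0.123). Dendritic cell and MHC class II genes (11 of 12 higher, median 1.13, adjusted p = 0.0155) included Clec9a (1.70 ± 0.58, adjusted p = 0.122) and Cd209a (1.86 ± 0.78, adjusted p = 0.149), and both lists were higher on 5 of 5 slides. The type I interferon response was higher in 17 of 17 genes (median 0.80, adjusted p = 0.00121, 1 rising adjusted over the list alone), with the antiviral gene Oas2 at 1.79 ± 0.49 (adjusted p = 0.120). The interferon gamma response was higher in 13 of 15 genes (median 0.79, adjusted p = 0.00787, 6 rising adjusted over the list alone), with Irgm1 at 0.79 ± 0.23 and Ido1, which degrades tryptophan, at 1.12 ± 0.34 (adjusted p = 0.120 for both). Within slides the type I interferon list was higher on 4 of 5 (-0.21 to 3.18) and the interferon gamma list on 3 of 5 (-0.20 to 2.31). Each of these 5 lists had an adjusted p of 0.693 with an estimated correlation. Their medians with slide as a block were 1.70, 1.20, 1.76, 1.42 and 1.0, all past the threshold. The arrays labelled wild-type stroma 65 and 82, which lay among the tumor arrays, moved these lists little: without them the medians were 1.26, 0.97, 0.89, 0.74 and 0.85, all still called. Without the 3 stroma arrays against their sex label B cell markers stayed called (1.55, adjusted p = 0.0334), and the other 4 did not (0.69, 1.21, 0.70 and 0.85, adjusted p = 0.0981, 0.105, 0.0943 and 0.0989).

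Tissue markers and proliferation genes moved more with those 2 arrays. All 17 skeletal muscle markers were higher in knockout stroma (median 1.70, adjusted p = 7.17e-04), as were all 15 adipocyte markers (1.40, adjusted p = 0.00121), and all 17 cell cycle genes were lower (-1.56, adjusted p = 7.17e-04). Schwann cell and nerve markers (9 of 10 higher, median 1.28, adjusted p = 0.0274), endothelial genes (14 of 14, 0.60, adjusted p = 0.00638) and immediate early genes (12 of 12, 0.70, adjusted p = 0.0339) were also called, and ribosomal proteins were lower in 17 of 18 genes (-0.35, adjusted p = 7.17e-04). The lowest cell cycle level in stroma was that of wild-type stroma 9 (-3.41), and without the 3 stroma arrays against their sex label, of which it is 1, the median was -2.76 (adjusted p = 9.40e-08). All 7 lists had an adjusted p of 0.693 with an estimated correlation, and in none did a member pass over all genes or adjusted over the list alone. Without wild-type stroma 65 and 82 the skeletal muscle median was 0.30, the adipocyte median 0.37, the cell cycle median -0.33 and the Schwann cell median 0.06 (adjusted p = 0.105, 0.0815, 0.213 and 0.472). The endothelial median was then 0.18 and the immediate early median 0.33 (adjusted p = 0.0829 and 0.0621), while ribosomal proteins stayed at -0.29 (adjusted p = 5.62e-05). The male-labelled wild-type arrays left in that fit were 4 and 9, and 9 also had the highest muscle level in stroma (9.01), so these medians depend on it too. Examples were Atp2a1, the calcium pump of fast muscle (2.47 ± 1.01, adjusted p = 0.144), Pparg, the master regulator of fat cells (1.26 ± 0.59, adjusted p = 0.180), the mitotic kinase Aurka (-1.45 ± 0.54, adjusted p = 0.128), the myelin gene Mbp (0.89 ± 0.28, adjusted p = 0.120) and Rps6 (-0.61 ± 0.17, adjusted p = 0.120), each in the direction of its list on 8 of 8 arrays. The endothelial receptor Tek was at 1.21 ± 0.46 (adjusted p = 0.132) and Junb at 0.55 ± 0.19 (adjusted p = 0.122). On 4 of 5 slides muscle, fat, nerve and endothelial lists were higher and cell cycle genes and ribosomal proteins lower, and immediate early genes were higher on 3 of 5. Further, with slide as a block the medians of muscle, fat, nerve, endothelial and cell cycle genes were 1.51, 1.46, 1.18, 0.60 and -1.11. Immediate early genes were no longer called with that block (0.39, adjusted p = 0.128). Of 100 random groupings of the stroma arrays, 54 gave as many called lists as the 12 of the labels, so the number of lists alone does not set the genotypes apart.

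**Figure D2:**
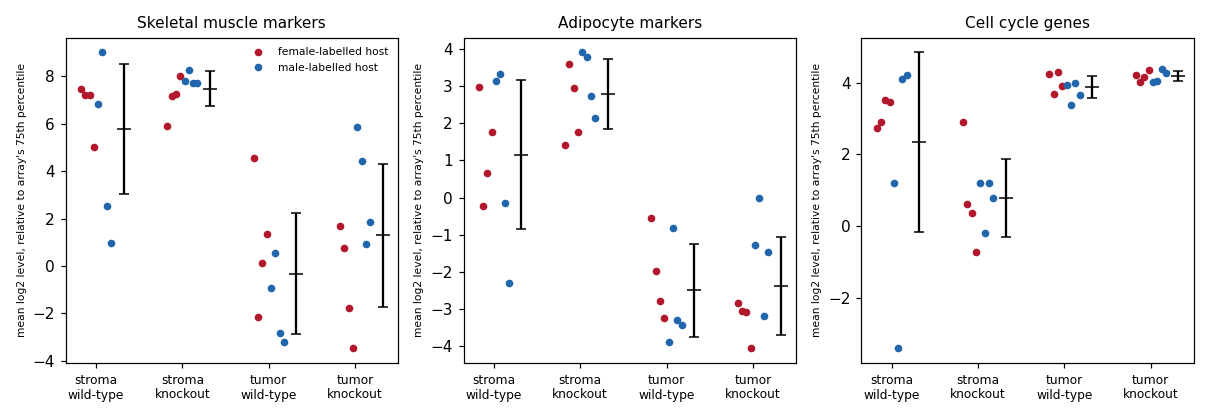
Mean log2 level of the skeletal muscle, adipocyte and cell cycle lists by group, relative to each array's 75th percentile; points are arrays, bars are the mean ± SD of 8 arrays. Cell cycle genes averaged 2.34 ± 2.51 in wild-type stroma, 0.77 ± 1.09 in knockout stroma, 3.89 ± 0.31 in wild-type tumor and 4.19 ± 0.15 in knockout tumor.

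The other 20 lists tested in stroma were not called. Medians were 0.78 for cAMP-responsive genes, 0.48 for T cell markers, 0.36 for cytotoxic and NK cell genes, 0.45 for MHC class I presentation, 0.79 for inflammatory cytokines and chemokines, 0.69 for immune checkpoint genes and 0.71 for mast cell markers. They were 0.61 for smooth muscle and pericyte markers, 0.20 for fibroblast and matrix genes, -0.25 for matrix-remodelling enzymes, 0.29 for keratinocyte markers, 0.89 for simple epithelium markers and 0.38 for erythroid genes. For p53 targets the median was 0.70, for oxidative phosphorylation 0.25 and for reference genes -0.19. In 3 uncalled lists the signs differed: neutrophil markers had a median of 0.03, a mean of -0.15 and a test pointing down, hypoxia and glycolysis genes a median of -0.19, a mean of 0.01 and a test pointing down, and the chromosome neighbours of Ptger2 a median of 0.05, a mean of -0.11 and a test pointing down. Adjusted over the list alone, 2 immune checkpoint genes and 1 hypoxia gene rose, and 3 hypoxia genes, 1 mast cell marker and 1 reference gene fell. Of the 6 sex-linked genes 1, Xist, was tested in stroma.

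In stroma 0 of 24781 genes passed limma at an adjusted p under 0.05, where 6999 (28.2%, 2947 higher and 4052 lower) had an unadjusted p under 0.05 and the smallest adjusted p was 0.113. With array weights 16148 genes passed (8659 up), with all 32 arrays in 1 fit 4336 (1100 up), and with replicate number added to that fit as a random block 4477. Female hosts alone gave 0 genes and 5144 (25.3%) at an unadjusted p under 0.05, male hosts alone 0 and 698 (3.86%). Without the 3 stroma arrays against their sex label 5516 passed. Leaving out 1 array gave 8333 genes without wild-type stroma 9, 5123 without wild-type stroma 4, 8 without knockout stroma 12 (among them Tnfaip2 at 1.72 and Hoxa11 at -3.40) and 0 without any other. Without wild-type stroma 65 and 82, 0 genes passed and 1854 (7.58%) had an unadjusted p under 0.05. A fixed block for slide gave 0 genes and 4715 (19.0%) at an unadjusted p under 0.05. By the 75th percentile of bright probes the median of all genes was 0.16, against 0.08 in the scaling used here. By exact permutation of list means, B cell markers (1.34, p = 0.00559), p53 targets (0.64, p = 0.00575), ribosomal proteins (-0.35, p = 0.00824) and endothelial genes (0.56, p = 0.0469) came out lowest of 32 lists, with a smallest adjusted p of 0.0879. No list passed fry (smallest adjusted p 0.171).

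The comparison of tumors grown in knockout and wild-type hosts asked whether the host receptor changed the tumor itself. No gene passed, while lymphocyte, antigen presentation and interferon lists were higher and neutrophil markers lower in knockout hosts. With an estimated correlation no list was called (adjusted p of 0.452 or more). A few arrays held the extremes: T cell markers were highest in knockout tumor 81 (-0.09) and 51 (-0.36), cytotoxic genes in knockout tumor 51 (1.18) and 81 (0.71), and neutrophil markers in wild-type tumor 82 (1.80), 65 (1.31) and 9 (1.19). Knockout tumor 51 and 81 were also the highest tumor arrays for the interferon gamma (4.28 and 3.57) and type I interferon lists (3.035 and 2.46). The same held for MHC class I presentation (5.35 and 4.47) and dendritic cell and MHC class II genes (1.835 and 2.47). No fit left out both arrays. Of the 17 type I interferon genes 17 were higher (median 0.77, camera adjusted p = 6.62e-08), with Ifit2 at 0.67 ± 0.26 and Ifih1, a sensor of viral RNA, at 0.81 ± 0.34. Interferon gamma response genes were higher in 14 of 15 (1.25, adjusted p = 4.06e-08), with the feedback inhibitor Socs1 at 0.55 ± 0.23 and Irf8 at 1.06 ± 0.45. T cell markers were higher in 12 of 14 (0.91, adjusted p = 4.42e-07), with Cd5 at 0.91 ± 0.33 and Cd2 at 1.29 ± 0.48. Cytotoxic and NK cell genes were higher in 10 of 12 (1.01, adjusted p = 7.92e-06), with Ifng, the interferon gamma gene, at 1.94 ± 0.75 and Xcl1 at 1.34 ± 0.57. Dendritic cell and MHC class II genes were higher in 10 of 10 (1.0, adjusted p = 1.49e-06), with Ccr7 at 0.96 ± 0.40 and H2-DMb1 at 0.54 ± 0.23. MHC class I presentation was higher in 11 of 11 (0.53, adjusted p = 1.79e-05), with the immunoproteasome subunit Psmb8 at 0.88 ± 0.42 and the peptide transporter Tap2 at 0.60 ± 0.31. B cell markers (5 of 6, 0.72, adjusted p = 0.0378) included Cd79b at 1.01 ± 0.46, and macrophage markers (16 of 18, 0.61, adjusted p = 0.00117) the complement genes C1qb at 0.74 ± 0.45 and C1qc at 0.75 ± 0.45. With an estimated correlation the adjusted p was 0.531 for macrophage markers and 0.465 for the other 7 of these lists.

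Neutrophil markers were lower in 11 of 11 genes (median -0.87, adjusted p = 1.10e-07, 0.452 with an estimated correlation), among them the chemokine receptor Cxcr2 (-1.43 ± 0.51) and Retnlg (-1.86 ± 0.71). Cell cycle genes were higher in 17 of 17 (0.33, adjusted p = 8.80e-11, 0.452 with an estimated correlation), with Aurka at 0.45 ± 0.14 and Foxm1, a driver of mitotic genes, at 0.37 ± 0.14. Skeletal muscle markers were higher in 17 of 17 (1.74, adjusted p = 4.42e-07, 0.477 with an estimated correlation), at mean levels of 1.29 ± 3.02 against -0.32 ± 2.56 (SD, n = 8 each). Oxidative phosphorylation was higher in 19 of 20 (0.10, adjusted p = 0.00554, 0.777 with an estimated correlation) and hypoxia genes lower in 14 of 15 (-0.19, adjusted p = 4.30e-04, 0.478 with an estimated correlation). Ribosomal proteins were lower in 18 of 18 (-0.19, adjusted p = 4.92e-05, 0.531 with an estimated correlation), but stood at -0.01 and were not called with quantile scaling, and Rps18 turned from -0.26 ± 0.16 to 0.02 with normexp correction. No member of any list passed over all genes or adjusted over the list alone.

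With slide as a block 9 lists were called in tumor, among them endothelial genes (0.47), immediate early genes (0.63) and the chromosome neighbours of Ptger2 (0.19). Medians were then 0.94 for T cell markers, 0.59 for dendritic cell genes, -0.96 for neutrophil markers, 0.36 for cell cycle genes, 2.22 for skeletal muscle and 0.22 for oxidative phosphorylation, all called. Those of the type I interferon (0.45, adjusted p = 0.0595), interferon gamma (0.50, 0.180), cytotoxic (0.66, 0.180), MHC class I (0.29, 0.169), macrophage (0.46, 0.196) and B cell lists (0.70, 0.719) were not. Hypoxia genes and ribosomal proteins also lost their call. Both genotypes shared only 3 slides, of which slide 2 set wild-type tumor 45, labelled female, against knockout tumor 81, labelled male. On these the type I interferon (0.11 to 1.47) and skeletal muscle lists (0.72 to 4.34) were higher on 3 of 3 and T cell markers on 2 (-0.49 to 2.90), as were the B cell, dendritic cell, MHC class I, interferon gamma, cell cycle and oxidative phosphorylation lists. Cytotoxic genes (-0.49 to 2.66) and macrophage markers (-0.34 to 2.51) were higher on 1 of 3. Neutrophil markers were lower on 2 (-1.80 to 0.41), and hypoxia genes and ribosomal proteins on 1. The lists not called without a block included cAMP-responsive genes (median -0.12), inflammatory cytokines and chemokines (-0.25), immune checkpoint genes (0.45), endothelial genes (0.19), fibroblast and matrix genes (0.02) and adipocyte markers (0.37). Mast cell markers had a median of 0.06, a mean of -0.12 and a test pointing down, and reference genes, at 0.01, and erythroid genes, at 0.08, also had a test pointing down, while Schwann cell markers had a median of 0.10, a mean of -0.03 and a test pointing up. Of 100 random groupings of the tumor arrays, 44 gave as many called lists as the 14 of the labels.

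Single genes with the smallest p were Rnase4 (1.54 ± 0.38), Helt (0.97 ± 0.28), Usp44 (0.57 ± 0.14), Ncoa7 (0.53 ± 0.13) and Fhod3, a formin of striated muscle (0.49 ± 0.13), each higher on at least 7 of 8 arrays. Lower were Mirt2 (-1.98 ± 0.55), Fam13c (-1.46 ± 0.39), Gdpd2 (-1.43 ± 0.37), Ccbe1, which acts in lymphatic growth (-0.92 ± 0.25), and Cstad (-0.62 ± 0.17), each on at least 7 of 8 arrays. All 10 and every list member above had an adjusted p of 0.976. In tumor 0 of 23749 genes passed limma, 787 (3.31%) had an unadjusted p under 0.05, and 0 passed with array weights (1859 at an unadjusted p under 0.05), with slide as a block (943) or under any other setting tried. Leaving out 1 array gave 412 (without wild-type tumor 5, the array with most outlier spots) to 1316 (without wild-type tumor 1) at an unadjusted p under 0.05. By exact permutation the cell cycle list (0.30, p = 0.0232) and neutrophil markers (-0.94, p = 0.0485) were lowest of 32, with a smallest adjusted p of 0.523. With no filter on dim probes the median of all genes was -0.21, against 0.00 with it.

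The genotype by tissue interaction asked whether the genotype difference itself differed between stroma and tumor. No gene passed. Genes named for the smallest p were Col6a5, a collagen VI chain (3.48 ± 0.66), Cyp4f14 (4.19 ± 0.96), the urate transporter Slc2a9 (2.14 ± 0.50), Tnfaip2 (1.63 ± 0.36) and Ptgir (1.62 ± 0.39) on the positive side. On the negative side were Hoxa11 (-3.02 ± 0.62), Phex (-2.47 ± 0.53), Hoxa11os (-2.35 ± 0.48), Enoph1 (-1.29 ± 0.27) and Dusp7, a phosphatase of ERK (-1.26 ± 0.25), all 10 with an adjusted p of 0.117. Of the lists, 2 were called: all 17 cell cycle genes were more negative in stroma (median -1.89, camera adjusted p = 2.26e-05, 1 falling adjusted over the list alone) and all 15 adipocyte markers more positive (1.28, adjusted p = 0.0335). With an estimated correlation the adjusted p was 0.991 for both. With slide as a block these medians were -1.08 and 1.13, both still called, and 13 lists were called in all. The immune lists called in both tissues were not called here, with a median of 0.00 for the type I interferon response (adjusted p = 0.835), although with slide as a block this list was called (1.10, adjusted p = 0.00664). T cell markers, called in tumor but not in stroma, were not called here either (-0.38, adjusted p = 0.698). Immune checkpoint genes had a median of 0.03, a mean of -0.11 and a test pointing down, and fibroblast genes -0.04, -0.03 and up.

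For this interaction 0 of 27120 genes passed limma and 5713 had an unadjusted p under 0.05. With array weights 13205 genes passed and without the arrays against their sex label 2138. Leaving out 1 array gave 5282 genes without wild-type stroma 9, 2511 without wild-type stroma 4, 979 without knockout stroma 12, 1 without wild-type tumor 45 (Col6a5, 3.79) and 0 without any other. With slide as a block 0 passed and 3093 had an unadjusted p under 0.05, and without wild-type stroma 65 and 82 these were 0 and 2146. By the 75th percentile of bright probes the median of all genes was 0.25, against 0.09 in the scaling used here.

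Stroma was compared with tumor to describe the tissues themselves. Stroma carried the genes of muscle, fat, nerve, vessels and mast cells, and tumor those of dividing cells. The largest rises in stroma were in muscle and fat genes: Ckm, the muscle creatine kinase (7.88 ± 0.84), Asb2 (7.55 ± 0.80), Car3 (7.51 ± 0.88), Trdn (7.48 ± 0.85), Mypn (7.47 ± 0.76), the fat cell protease Cfd (7.44 ± 1.01), Cox8b (7.39 ± 0.87), Pvalb (7.21 ± 0.85), Myot (7.20 ± 0.81) and Ampd1 (7.20 ± 0.73). Among the largest falls were the BMP antagonist Grem1 (-4.75 ± 0.65), Cck (-4.39 ± 0.54), Rasgrf1 (-4.38 ± 0.52), Wfdc2 (-4.29 ± 0.69), Gap43, of growing axons (-4.08 ± 0.71), the EGF receptor ligand Ereg (-4.06 ± 0.66), Crhbp (-4.05 ± 0.64), Hapln1 (-4.01 ± 0.50) and Foxa1 (-3.95 ± 0.46). Each of these 19 genes had an adjusted p of 1.69e-05 or less and its direction on at least 14 of 16 arrays.

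By list, 17 of 17 skeletal muscle markers rose (median 6.28), 14 of 15 adipocyte markers rose (4.01, Lpl by 2.56 ± 0.31 with an adjusted p of 1.81e-07), and 8 of 10 Schwann cell markers rose (3.07, S100b by 3.75 ± 0.49 with an adjusted p of 4.78e-07). Of the mast cell markers 7 rose and 1, Gata2, fell (1.89, the mast cell protease Mcpt4 by 2.87 ± 0.30). Smooth muscle and pericyte markers rose in 7 of 9 (1.57, Myh11 by 3.67 ± 0.48, while Smtn fell by 0.57), and endothelial genes in 12 of 14 (1.39, Vwf by 2.0 ± 0.30, while Vegfa fell by 0.73). B cell markers rose in 6 of 9 (1.54, Ms4a1 by 2.67 ± 0.48). Macrophage markers rose in 12 of 18 (1.37): Retnla, a marker of alternative activation, by 6.43 ± 0.72 and Cd163 by 5.29 ± 0.63, while Arg1 fell by 2.42. Dendritic cell genes rose in 7 of 12 (1.52, Cd209a by 4.50 ± 0.62, while Flt3 fell by 1.11), type I interferon genes in 5 of 17 (0.81, Oas2 by 2.0 ± 0.42), erythroid genes in 7 of 7 (1.47, Hbb-b1 by 1.95 ± 0.57) and p53 targets in 6 of 12 (1.19, Phlda3 by 3.01 ± 0.33, while Bax fell by 0.54). Simple epithelium markers rose in 4 of 8 (1.21, Krt18 by 5.26 ± 0.73, while Krt8 fell by 2.13), and Elf3, an epithelial transcription factor above background on no tumor array, was at least 1.86-fold higher. Oxidative phosphorylation genes rose in 10 of 20 (0.35, Ndufa1 by 0.90 ± 0.19, while Cox6a1 fell by 0.79).

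Cell cycle genes fell in 17 of 17 (median -2.64), Ccnb1, the mitotic cyclin, by 3.04 and Mcm2 by 1.81, and ribosomal proteins fell in 14 of 18 (-0.53), Rps3 by 1.06. These 16 lists had a camera adjusted p between 3.48e-10 (skeletal muscle) and 0.0321 (p53 targets), and between 0.420 and 0.742 with an estimated correlation. Adjusted over the list alone the counts of these 16 lists matched except for 7 simple epithelium markers, 7 p53 targets and 16 ribosomal proteins. Immediate early genes (median 0.60, 7 of 12 rose), prostaglandin pathway genes (0.16, 10 rose and 5 fell), cAMP-responsive genes (0.37, 7 rose and 5 fell), hypoxia genes (-0.60, 8 of 15 fell) and reference genes (-0.52, 8 of 12 fell) were not called as lists. Nor were inflammatory cytokines and chemokines (-0.46, 4 rose and 8 fell), fibroblast and matrix genes (0.37, 8 rose and 4 fell), matrix-remodelling enzymes (-0.17, 3 rose and 5 fell), T cell markers (0.12), cytotoxic genes (-0.23), MHC class I presentation (-0.13) or the interferon gamma response (0.19). Median, mean and test differed in sign for neutrophil markers (-0.11, -0.21, up), immune checkpoint genes (-0.29, 0.01, up), keratinocyte markers (0.11, -0.10, up) and Ptger2 neighbours (0.00, -0.04, up).

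Between stroma and tumor 17032 of 27120 genes passed limma, 6983 up and 10049 down, of which 4562 and 4311 changed at least 2-fold. A fixed block for slide gave 16752, 16310 of them shared. Leaving out 1 array at a time gave 16448 to 17270 genes, and without wild-type stroma 65 and 82 there were 17604. On 6 of 6 slides the muscle, fat, nerve, mast cell, endothelial, smooth muscle, B cell, macrophage, dendritic, erythroid, epithelial and p53 lists were higher and the cell cycle and ribosomal lists lower, while the type I interferon and oxidative phosphorylation lists were higher on 4. Reference genes differed between the tissues, and the scale is relative to the 75th percentile of each array.

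The sex labels were checked before the sexes were compared, with 2 probes of Xist, the RNA of the inactive X chromosome, and the Y-linked genes Ddx3y, Kdm5d and Uty. Against their labels stood 5 male-labelled arrays: the arrays labelled wild-type stroma 9, knockout stroma 95 and 99, and knockout tumor 95 and 99. The mean of the 3 Y-linked genes was -7.37 to -6.73 in these arrays, against -4.86 to -1.33 in the other male-labelled stroma arrays, -5.48 to -3.50 in the other male-labelled tumor arrays, -7.90 to -6.20 in female-labelled stroma and -7.47 to -6.13 in female-labelled tumor. The brighter Xist probe, kept under the name XIST and chosen after the values were seen, was at 3.17 to 3.69 in the 3 stroma arrays, where the other male-labelled stroma arrays were at -7.35 to -5.57 and female-labelled ones at 1.82 to 4.43. In the arrays labelled knockout tumor 95 and 99 it was at 0.52 and 0.48, against -7.34 to -5.87 in the other male-labelled and -0.53 to 1.09 in the female-labelled tumor arrays. The dimmer probe, matched to the symbol Xist, was at -2.24 to -1.47 in the 3 stroma arrays, where the other male-labelled stroma arrays were at -7.29 to -6.07 and female-labelled ones at -3.56 to -0.31. In knockout tumor 95 and 99 this probe was at -5.29 and -4.00, against -7.37 to -5.97 in the other male-labelled and -5.02 to -3.15 in the female-labelled tumor arrays. No female-labelled array had one of the 3 Y-linked genes well above background, nor had wild-type stroma 82 and wild-type tumor 9 and 65, labelled male and low in Xist. The further Y-linked gene Eif2s3y was at -3.64 in knockout tumor 95, above all female-labelled tumor arrays (-7.32 to -4.41) and below the other male-labelled ones (-2.04 to -0.03), and at -5.04 in knockout tumor 99. In stroma it was at -2.01 in the female-labelled wild-type stroma 5, against -6.14 to -5.00 in the other female-labelled arrays and -1.58 to 2.40 in the male-labelled ones not against their label. In the stroma arrays against their label it was at -6.21 (wild-type 9), -4.66 (knockout 95) and -5.55 (knockout 99).

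**Figure D3:**
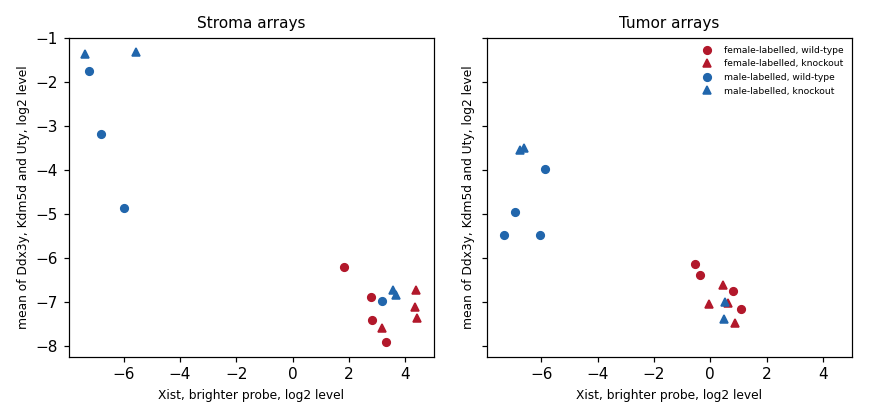
Log2 level of the brighter Xist probe against the mean of Ddx3y, Kdm5d and Uty, relative to each array's 75th percentile, for the 32 arrays by tissue and sex label. The 3 stroma arrays labelled male without signal of these 3 genes have Xist at 3.17 to 3.69, in the range of the female-labelled stroma arrays.

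The comparison of male with female hosts in stroma described sex differences in the tissue around the tumor, and no gene passed with the labels as given. Xist differed by -3.11 ± 0.88 (adjusted p = 1.0, lower on 6 of 8 male-labelled arrays) on the dimmer probe and by -6.19 ± 1.75 (adjusted p = 1.0) on the brighter one, and no other listed sex-linked gene was tested there. Ddx3y, Kdm5d and Uty were well above background on 4 of 8 male-labelled and 0 of 8 female-labelled arrays and were at least 2.36-fold, 1.56-fold and 1.52-fold higher in males. Other genes with a small p were Pde5a, which degrades cGMP (1.53 ± 0.37), Grb14 (1.02 ± 0.23), Emid1 (0.90 ± 0.25), Apc2 (0.72 ± 0.19) and Maoa, monoamine oxidase A (0.62 ± 0.15), higher in males on 8 of 8 arrays. Lower in males were Cyp4f14 (-3.02 ± 0.73), Zpld2 (-2.77 ± 0.72), Prrt3 (-2.68 ± 0.70), C2cd4b (-2.44 ± 0.60) and Spsb1 (-0.82 ± 0.21), each on at least 7 of 8 arrays (adjusted p = 1.0 for all 10). Type I interferon genes were lower in males in 17 of 17 (median -0.68, camera adjusted p = 2.85e-08), as were cell cycle genes in 17 of 17 (-0.87, 0.00148), neutrophil markers in 10 of 11 (-0.84, 0.00179), macrophage markers in 16 of 18 (-0.54, 0.00179), the interferon gamma response in 12 of 15 (-0.46, 0.00179), cytokines in 14 of 17 (-0.75, 0.00304), erythroid genes in 7 of 7 (-0.63, 0.00860), skeletal muscle in 16 of 17 (-0.63, 0.00864) and mast cell markers in 6 of 9 (-0.13, 0.0290). Smooth muscle markers (7 of 9 higher, 0.44, 0.00860) and oxidative phosphorylation (19 of 20, 0.18, 0.0400) were higher. All 11 lists had an adjusted p of 0.828 with an estimated correlation. Wild-type stroma 9, labelled male, had the lowest type I interferon (-0.57) and cell cycle levels (-3.41). The lowest muscle levels were those of male-labelled wild-type stroma 82 (0.97) and 65 (2.52). Otherwise the muscle list leaned the other way: 5 of 8 male-labelled arrays lay above the female median, and males were higher on 4 of 6 slides (median 0.41).

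Here 0 genes passed limma, 557 had an unadjusted p under 0.05 (1429 without wild-type stroma 9), and 1790 passed with array weights. With slide as a fixed block 551 had an unadjusted p under 0.05, and the type I interferon median was -0.66 (adjusted p = 6.40e-09), lower on 5 of 6 slides (-3.18 to 1.28). Without the 3 arrays against their label 4 genes passed, all lower in males, and 2 lists were called, with cytokines at 0.07 and oxidative phosphorylation at 0.03. Type I interferon genes (-0.39, adjusted p = 0.0628) and cell cycle genes (-0.14, adjusted p = 0.790) were then not called. These 4, named after the values were seen, were the dimmer (-4.96) and the brighter probe of Xist (-9.95), Chil1 (-3.94) and Gm36543 (-3.23). B cell markers (median 0.11, mean -0.01, test up) and fibroblast genes (-0.01, -0.03, up) differed in sign.

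In tumors the comparison of hosts labelled male and female described inflammation. Inflammatory cytokines and chemokines were higher in males in 18 of 19 genes (median 1.76, camera adjusted p = 1.33e-13, 12 rising adjusted over the list alone), with Il1b at 2.73 ± 1.78 against -0.13 ± 0.63 (SD, n = 8 each), a difference of 2.87 ± 0.62 (adjusted p = 0.338, 8 of 8 arrays). Il6 differed by 2.46 ± 0.64 (adjusted p = 0.444, 8 of 8 arrays). The cytokine list level was not high in all males: it was highest in wild-type tumor 82 (1.31), 9 (1.06) and 65 (0.98) and knockout tumor 81 (1.13). Male-labelled wild-type tumor 4 (-1.19) and knockout tumor 95 (-1.13) lay within the female-labelled range (-1.68 to -0.41). Immediate early genes were higher in 12 of 12 (1.05, adjusted p = 1.60e-15, 10 rising adjusted over the list alone), with the growth factor response gene Egr1 at 1.19 ± 0.20 (adjusted p = 0.273) and Junb at 0.92 ± 0.17 (adjusted p = 0.323), each on 8 of 8 arrays. cAMP-responsive genes (13 of 17, 0.67, adjusted p = 3.03e-07, 9 alone) included the nuclear receptors Nr4a1 (1.13 ± 0.26) and Nr4a2 (1.01 ± 0.22), and neutrophil markers (11 of 11, 1.15, adjusted p = 7.32e-08, 5 alone) the antimicrobial peptide Camp (1.21 ± 0.35) and Clec4d (1.79 ± 0.53). Matrix-remodelling enzymes (12 of 15, 0.89, adjusted p = 8.36e-07, 4 alone) included the macrophage elastase Mmp12 (2.28 ± 0.52), and prostaglandin pathway genes (13 of 17, 0.30, adjusted p = 3.12e-04, 4 alone) Ptgir (1.21 ± 0.26) and the phospholipase Pla2g4a (0.69 ± 0.21). With an estimated correlation these 6 lists had an adjusted p of 0.128. The cAMP list shares Fos, Fosb, Dusp1 and Nr4a1 with the immediate early list, and Il6 and Cxcl5 with the cytokine list. Results of these lists are therefore not independent. On 5 of 5 slides the cytokine (0.34 to 2.72), immediate early (0.75 to 2.34), cAMP (0.41 to 1.03), matrix-remodelling (0.34 to 1.68) and prostaglandin (0.11 to 0.93) lists were higher, and with slide as a block the cytokine and immediate early medians were 1.79 (adjusted p = 6.07e-17) and 1.05 (adjusted p = 1.69e-16). The slide counts do not separate sex from genotype, as on slide 2, where the male-labelled tumor array was knockout and the female-labelled one wild type.

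A further 9 lists were called in the tumors. Fibroblast and matrix genes (15 of 18 higher, 0.37, adjusted p = 8.58e-05, 0.161 with an estimated correlation) included Col1a1 (2.03 ± 0.75). Hypoxia genes (13 of 15, 0.36, 6.13e-04, 0.497 with an estimated correlation) included Hk2 (0.84 ± 0.25), the interferon gamma response (14 of 15, 0.53, 0.00357, 0.667 with an estimated correlation) Nos2 (1.62 ± 0.37), and macrophage markers (15 of 18, 0.42, 0.00552, 0.662 with an estimated correlation) Cd14 (1.18 ± 0.31). Mast cell markers (7 of 8, 0.68, 0.00569), p53 targets (9 of 11, 0.19, 0.00612), endothelial genes (9 of 13, 0.26, 0.0420) and smooth muscle markers (8 of 9, 0.19, 0.0481) were higher and cell cycle genes (15 of 17 lower, -0.13, 0.0292) lower, with an adjusted p of 0.285, 0.232, 0.667, 0.453 and 0.667 with an estimated correlation. Among single genes Osmr, the oncostatin M receptor (0.91 ± 0.14, adjusted p = 0.252, 8 of 8 arrays), Ugt1a6b (0.99 ± 0.17, 0.273) and Ccdc57 (1.22 ± 0.22, 0.323) were higher, and Plek2 (-1.05 ± 0.20, 0.330), Prss16 (-1.01 ± 0.22, 0.338), Gdf3 (-1.45 ± 0.31, 0.338), Aspa (-1.55 ± 0.34, 0.338) and Il17rd (-1.07 ± 0.24, 0.338) lower in males. The Y-linked Eif2s3y differed by 3.59 ± 0.67 (adjusted p = 0.323, 8 of 8 arrays), and Ddx3y, above background on 3 of 8 male-labelled and 0 of 8 female-labelled arrays, was at least 1.08-fold higher, while Kdm5d, Uty and the dimmer Xist probe were too dim to be tested. The brighter Xist probe differed by -5.17 ± 0.98 (adjusted p = 0.323).

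In tumor 0 genes passed limma between the sexes, 1718 had an unadjusted p under 0.05 (994 higher in males), and 24 passed with array weights (23 up). Without the arrays labelled knockout tumor 95 and 99, 25 passed (6 up), among them the brighter Xist probe (-6.97, adjusted p = 1.18e-06), and the cytokine median was 2.09. Without wild-type tumor 4, 52 genes passed (50 up), and without any other single array 0. With slide as a block 0 passed and 1748 had an unadjusted p under 0.05. By exact permutation the cytokine list differed by 1.44 (p = 0.0042), the immediate early list by 1.06 (p = 0.00435), matrix-remodelling enzymes by 0.99 (p = 0.00995), cAMP-responsive genes by 0.74 (p = 0.0112), fibroblast genes by 0.61 (p = 0.0132) and p53 targets by 0.32 (p = 0.0435), with a smallest adjusted p of 0.0696 over 32 lists. No list passed fry (smallest adjusted p 0.0588), and of 100 random groupings 44 gave as many called lists as the 15 of the labels.

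The genotype by sex interaction asked whether the knockout acted differently in male and female hosts. In stroma 0 genes passed, 178 had an unadjusted p under 0.05, and 1970 passed with array weights. Without wild-type stroma 9 there were 1791 (7.3%) at an unadjusted p under 0.05, and 1558 without the 3 arrays against their label. Genes named for the smallest p were, among positive values, Myh13, a muscle myosin (5.81 ± 2.27), Barx2 (4.16 ± 1.36), Ggt6 (3.91 ± 1.44), Timd4 (2.04 ± 0.78) and Cd82 (1.92 ± 0.68), and among negative ones Nlrp5 (-1.55 ± 0.54), Tatdn2 (-1.13 ± 0.44), Tgif2lx1 (-1.10 ± 0.40), Slc18a2, the vesicular monoamine transporter (-0.99 ± 0.32), and Zfp26 (-0.81 ± 0.32), all with an adjusted p of 1.0. Of 9 lists called, skeletal muscle (17 of 17 positive, median 2.57, camera adjusted p = 4.36e-12), cell cycle (1.80, 3.27e-05), type I interferon (1.02, 8.76e-06), interferon gamma (0.60, 1.84e-04), oxidative phosphorylation (0.36, 8.40e-04), adipocyte (0.61, 0.00656) and p53 (0.59, 0.0295) were positive and mast cell (-1.07, 2.20e-05) and endothelial (-0.40, 0.0293) negative. The muscle level was lowest in wild-type males 82 (0.97) and 65 (2.52). Male-labelled wild-type stroma 4 (6.86) and 9 (9.01) were near the male-labelled knockout stroma arrays (7.72 to 8.28). Of these arrays, wild-type stroma 9 and knockout stroma 95 and 99 stood against their sex label. With an estimated correlation the adjusted p ran from 0.637 for skeletal muscle, p53 and mast cell markers to 0.756. Without the arrays against their label the cell cycle median was -0.30. T cell markers had a median of -0.19, a mean of 0.01 and a test pointing down, cytokines -0.13, 0.00 and up, and B cell markers -0.10, 0.10 and up. In a fit with slide as a block 336 genes had an unadjusted p under 0.05 and 0 passed.

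In tumor 0 genes passed and 1238 had an unadjusted p under 0.05. Pvalb (8.69 ± 2.35), Tcap (8.35 ± 2.21) and Prr33 (5.34 ± 1.41), all muscle genes, and Atp6v0e2 (2.95 ± 0.80) and Gpr183 (1.86 ± 0.47) were positive. Gabrd (-1.99 ± 0.56), the inflammatory caspase Casp4 (-1.44 ± 0.40), the gap junction gene Gja1 (-1.38 ± 0.39), Jun (-1.11 ± 0.28) and Wdr60 (-0.93 ± 0.24) were negative, all 10 with an adjusted p of 0.857. Of 17 lists called, skeletal muscle was the most extreme (17 of 17 positive, median 6.76, camera adjusted p = 6.04e-23, 16 rising adjusted over the list alone, 0.185 with an estimated correlation). Its highest levels were in 3 arrays, knockout male 15 (5.88) and 81 (4.45) and wild-type female 1 (4.58), against -3.46 to 1.86 in the other 13. Mast cell (1.64), B cell (1.45), erythroid (1.28), adipocyte (1.05), Schwann cell (0.90), T cell (0.84), cytotoxic (0.79), dendritic cell (0.70) and cell cycle lists (0.27) were positive. Cytokine (-1.09), hypoxia (-1.04), neutrophil (-0.86), MHC class I (-0.57), cAMP (-0.57), ribosomal (-0.56) and reference lists (-0.40) were negative, with an adjusted p of 0.185 to 0.689 with an estimated correlation for these 16. Ribosomal and reference genes turned with quantile scaling, to 0.01 and 0.04. The skeletal muscle median was 7.14 with slide as a block and 8.57 without knockout tumor 95 and 99, without which 7 genes passed, all positive, among them Prr33 (7.60) and Atp6v0e2 (4.12). Endothelial genes had a median of 0.19, a mean of -0.14 and a test pointing down, and fibroblast genes -0.12, 0.19 and down. In a fit with slide as a block 1050 genes had an unadjusted p under 0.05 and 0 passed.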

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

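All tests in this part were chosen after the result was seen, except the 3 list means as covariates for the first pattern and slide as a block for the first and the third. For the fit without arrays against their sex label, itself chosen after seeing the data, only the prediction came before its result. An outlier rule of this kind marks about 1 in 20 groups by chance, and it marked 38 of 788 (4.82%).

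Knockout stroma lay further from tumor than wild-type stroma, in part through wild-type stroma 65 and 82, without which 7.58% in place of 28.2% of genes had an unadjusted p under 0.05. The male-labelled wild-type arrays left in that fit were 4 and 9, and 9 lay at the other extreme (muscle list 9.01, cell cycle list -3.41). Female hosts alone, with neither 65 nor 82, gave 25.28% and male hosts alone 3.86%, so the difference does not rest on 65 and 82 only. All 16 lists called between the tissues differed between the genotypes in the same direction, 14 of them by more than 1 SE, which could reflect less tumor tissue in the knockout stroma pieces. Over all genes the genotype difference correlated with the tissue difference at 0.883. Random groupings of the stroma arrays gave a median absolute correlation of 0.541 and at most 0.881. Of 100 groupings only 1, the labels' own, had a correlation as large. The margin to the next was small, and sizeable correlations also arose without the genotype labels. With the means of the muscle, fat and keratinocyte lists as covariates 8.297% of genes still had an unadjusted p under 0.05, which cannot tell whether that is the cause. Slide differences alone are argued against by 19.03% of genes with slide as a block. Whether dissection or genotype set the content of the pieces stays open.

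Male-labelled arrays without signal of Ddx3y, Kdm5d and Uty numbered 5. A wrong sex or animal label may explain them, as 5 had the brighter Xist probe at or above the lowest female-labelled array of their tissue. A swap within the series is argued against by 0 female-labelled arrays with this probe at or below the highest of the other male-labelled arrays. Loss of the Y chromosome is argued against by gaps of 8.73 log2 in stroma and 6.35 in tumor to the other male-labelled arrays. The animals behind these labels stay open, also as Eif2s3y in knockout tumor 95 (-3.64) lay above all female-labelled tumor arrays. In knockout stroma 95 (-4.66) it lay above all female-labelled stroma arrays except wild-type stroma 5.

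The cytokine and immediate early lists were higher on average in tumors of hosts labelled male, with the highest cytokine levels in wild-type tumor 9, 65 and 82 and knockout tumor 81. Arrays against their sex label do not account for it, since the cytokine median was 2.09 without them, nor does slide, with 1.79 as a block. Whether it arose by chance stays open, since by exact permutation both lists had an adjusted p of 0.0696 (p = 0.0042 and 0.00435, n = 8 each).

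Random groupings of the arrays, 100 per comparison and counting the labels' own, were compared with the labels only to see whether chance can be excluded. Missing values were filled with group means for these fits, so the labels' own numbers differ slightly from those of the report. As many genes at an unadjusted p under 0.05 came from 4 groupings for genotype in stroma (7005 genes by the labels, 8127 at most otherwise) and 4 for genotype by tissue (5722, 8180). Other groupings thus reached more genes, and these numbers were not corrected for the comparisons made, so chance is not excluded for these 2 either. They came from 51 for genotype in tumor (791, 6442), 56 for sex in stroma (557, 6520), 17 for sex in tumor (1722, 8065), 77 for genotype by sex in stroma (180, 8243) and 26 for genotype by sex in tumor (1243, 4823), where chance is not excluded. For stroma against tumor 1 grouping, the labels' own, had as many genes past the adjusted threshold (17041, 8782 at most otherwise). As many lists came from 54 groupings for genotype in stroma (12 lists, 25 at most otherwise), 44 for genotype in tumor (14, 25), 99 for genotype by tissue (2, 24), 17 for stroma against tumor (16, 25), 52 for sex in stroma (11, 23), 44 for sex in tumor (15, 24), 67 for genotype by sex in stroma (9, 21) and 21 for genotype by sex in tumor (17, 24), so chance is excluded for none of these numbers of lists. Groupings that call many genes point to a structure of the samples.

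Wild-type stroma 9 had Atp5a1 at 8.81, Bbc3 at -0.33, Ccnb1 at -6.88, Cox6a1 at 6.73, cell cycle genes at -3.41 and oxidative phosphorylation at 7.71. Knockout stroma 12 had Gnpnat1 at 1.17, Rpl8 at 7.87, Rps3 at 7.35, Rps6 at 7.78, Snhg12 at 1.78 and skeletal muscle markers at 5.90. Wild-type tumor 1 had Asb2 at 1.21, Eno3 at 5.05, Hapln1 at -2.97 and Lpl at 1.81. Knockout stroma 15 had Elf3 at -4.63, Pmp22 at 5.35, Prrt3 at -7.24 and Zpld2 at -6.30. Wild-type tumor 9 had Aurkb at 0.80, Ifit2 at -2.25 and Pcna at 4.04. Wild-type stroma 82 had Cd163 at -3.45 and Cd209a at -6.05, and wild-type stroma 4 had Cd22 at -1.40 and Ptger1 at -2.54. Wild-type tumor 45 had Cdkn3 at 2.69 and Ndufa4 at 5.51, and wild-type tumor 82 had Rsad2 at 1.22. Knockout stroma 81 had Pde5a at 0.51 and Pecam1 at -1.46. Knockout tumor 99 had Camp at -1.99, knockout tumor 12 had Flt3 at 1.21, knockout tumor 15 had Krt8 at -2.10, knockout tumor 95 had Mcm2 at 3.05, and knockout tumor 81 had prostaglandin pathway genes at -0.16.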

How the results depend on the processing

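The fits without certain arrays and the exact permutation were chosen only after the result was seen. For genotype in stroma the count of 0 became 16148 with array weights, 4336 with all arrays in 1 fit, 4477 with replicate number added to that fit as a random block and 5516 without arrays against their sex label, and leaving out 1 array gave 0 to 8333. Genotype in tumor stayed at 0 throughout. Genotype by tissue gave 13205 with array weights, 2138 without arrays against their sex label, and 0 to 5282 leaving out 1 array. For stroma against tumor there were 10978 with the filter on all arrays, 8873 at least 2-fold, and 16448 to 17270 leaving out 1 array. Sex in stroma gave 1790 with array weights and 4 without arrays against their label (0 to 0 leaving out 1), and sex in tumor 24, 25 and 0 to 52. Genotype by sex gave 1970 in stroma with array weights and 7 in tumor without arrays against their label, with 0 to 0 leaving out 1. The cause was not tested. Of 252 values of named genes 81 were stronger with array weights, and 43 of 251 without arrays against their label. Ptger2 in the genotype comparisons was counted apart, and in stroma it was also stronger with array weights (0.87, adjusted p = 0.0128).

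Camera with an estimated correlation called 0 lists in every comparison, fry 16 for stroma against tumor and 0 elsewhere, and the exact permutation 0 in the 4 comparisons tested. With the preset correlation, genotype in stroma called 12 lists and 7 without arrays against their label, genotype in tumor 14 and 9 with slide as a block, and genotype by tissue 2, with 4 after normexp correction, 4 by quantile scaling, 13 with slide and 4 without arrays against their label. Sex in stroma went from 11 to 2 without those arrays, and genotype by sex in tumor from 17 to 11 by quantile scaling and 11 with slide. The cause was not tested.

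Signs were reversed for Ptger3 in stroma (-0.02 by normexp, -0.73 without wild-type stroma 65 and 82), and for Ptges in stroma (0.00 by normexp, 0.01 by quantile, 0.07 by bright probes, 0.02 with array weights, 0.17 without arrays against their label). In tumor they were reversed for Ptgs1 (0.02 by quantile, 0.12 with array weights, 0.04 without arrays against their label), Ptgs2 (0.12 without those arrays), Ptges (0.06 with slide) and Rps18 (0.02 by normexp). Among lists they were reversed for adipocyte markers by genotype in stroma (-0.02 with covariates) and, without arrays against their label, for cytokines (0.07) and the test direction of oxidative phosphorylation (0.03) by sex in stroma and cell cycle genes by genotype and sex in stroma (-0.30). The adipocyte list's own mean was among those covariates, which holds its difference near no change. Its turned sign therefore tells nothing. By genotype and sex in tumor they were reversed for cytotoxic genes (-0.05 with slide), the test direction of cAMP (-0.23) and cytokine lists (-0.37) without arrays against their label, and ribosomal (0.02 by normexp, 0.01 by quantile) and reference genes (0.05 and 0.04).

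As a random block slide had a correlation of 0.0226 in stroma, 0.00551 in tumor and 0.00326 over all arrays, and replicate number 0.107. The replicate number as a fixed block gave 16226 genes for stroma against tumor, and 17061 with knockout stroma 49 paired with the unmatched knockout tumor array, and 0 for genotype by tissue in both. Over 15 possible pairs and 21549 probes, stroma and tumor of the same number correlated at -0.096 to 0.549 (median 0.115), 8 of them above 0.1, and 5 matched best with their own number. The lowest was number 9, whose stroma and tumor arrays differed in the mean of the Y-linked genes (-6.98 and -3.97) and in the brighter Xist probe (3.17 and -5.87), which argues against 1 animal with 1 right label. Numbers 95 and 99 were against their label in both stroma and tumor, as 1 animal per number would give, but sex does not identify an animal. Whether these and the remaining numbers pair stays open. The series matrix was not run for stroma against tumor, because it is centred within tissue, and Ptger2 had a single probe, so no other probe was tried. A signal over background limits what can be said of dim probes such as that of Ptger2.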

Other observations

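Muscle genes varied widely among the tumor arrays. The skeletal muscle list averaged -0.32 ± 2.56 in wild-type and 1.29 ± 3.02 in knockout tumor (SD, n = 8 each), while cell cycle genes varied little there (3.89 ± 0.31 and 4.19 ± 0.15). In wild-type stroma the muscle list was at 5.79 ± 2.75 and in knockout stroma at 7.48 ± 0.73, and the lowest wild-type stroma arrays were 65 (2.52) and 82 (0.97).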
